A study of Caenorhabditis elegans with 2 samples.

How the data were processed

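Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole young adult worms with the Y53F4B.3 protein tagged at its own locus, in 2 biological replicates of 1 group, per the labels. Each replicate came with a ranked list of candidate peaks and a thresholded list, and the series with 2 ranked and 2 thresholded lists that draw on both replicates, a larger and a conservative one, making 8 lists. Per the authors' read-me texts the lists are on assembly ce11, and each thresholded list draws on 1 input file that no ranked list uses, whose nature is not stated. The aligner, the peak caller, the IDR tool and their versions are not given in the sources used here. The control library and reads were not analysed here, and the read depth per sample is unknown.

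The signal value of a peak is a score that the authors' peak caller gave, with no scale shared between lists, so it was used only to rank and describe peaks within 1 list. A second score in the deposited lists is the irreproducible discovery rate (IDR) as 125 times its negative log2, capped at 1000. The ranked lists also give the -log10 of the global IDR as the authors computed it, capped at 5. The summit position is deposited as an offset in bp from the peak start. The p-value column of the deposited lists holds -1 throughout and was not used, and neither were the q-value, the local IDR and 8 columns of sub-list values in each ranked list of 20 columns, which carry no names. Every peak in the thresholded lists was found in its ranked list with an IDR of 0.01 or less. The thresholded lists omit some peaks that meet this limit, 149 in the larger set, 102 in the conservative set, 81 in replicate 1 and 154 in replicate 2; they entered neither the listed peaks nor the background.

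Gene positions came from Ensembl release 115. A summit was placed in the first matching class of promoter (up to 500 bp upstream of a protein-coding transcription start site or 100 bp inside), 5' UTR, coding exon, 3' UTR, intron, non-coding RNA gene and intergenic. Pseudogenes counted as intergenic. Each summit was assigned to the protein-coding gene with the nearest start site within 2000 bp, and to a class of short RNA genes within 500 bp. The background of each test was the candidates of the same ranked list that did not pass, since these were ranked together with the listed peaks. If fixed regions were left out of the thresholded lists, non-passing candidates within them could not have been listed. Such candidates were not removed from the background. Classes, chromosomes, short RNA genes and 29 gene lists were tested by Fisher's exact test, two-sided, with conditional odds ratios, exact 95% limits and Benjamini-Hochberg adjustment within each family of 7 classes, 6 chromosomes, 7 kinds of short RNA gene or 29 lists. Gene lists were tested over genes, not peaks. Peaks counted as shared where they overlapped by 50% of the shorter one. Shares have exact binomial (Clopper-Pearson) 95% intervals. Canonical 6-mers within 50 bp of the summit were tested by presence against 5 candidates per peak matched to within 2 points of GC content, drawn with a fixed seed. The repeat share was computed from the reference genome as the percentage of 24-mers within 130 bp of the summit that occur 5 or more times; it describes sequence and not the authors' read filter. Peaks, neighbouring genes and overlapping words are not independent, so adjusted p-values describe these lists rather than a population of animals.

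The grouping, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule names the gene of each of the 20 listed peaks of the larger set with the highest signal, up to 3 members with the highest peak signal of each list with an adjusted p under 0.05, the tagged gene whatever its value, and the gene of the 3 strongest peaks of each replicate that the other does not share. A peak with no start site within 2000 bp is named by position. The alternatives were other overlap rules, the conservative set, each replicate's own lists, promoters of 1000 bp, a background matched on chromosome and GC content, windows of 200 bp and 500 bp, all protein-coding genes as background, flanks of 100 bp, 8-mers, and unmatched candidates. A stricter IDR of 0.01 was also planned, but the authors' threshold is already there, so it removes no peak. An IDR of 0.001, the addition of the left-out peaks, peaks listed in both replicates, summits with a repeat share of 0, and removal of summits near short RNA genes were chosen after seeing the data.

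The tests were tested on simulated data, 20 runs with planted effects and 20 without, each drawing 465 peaks from 9328 candidates of the larger set. With planted odds of 8, the median recovered tRNA odds ratio was 8.84, the tRNA class was called in 20 runs, ribosomal proteins in 17 runs, and a 6-mer planted in 20% of the windows ranked first in 20. Without a planted effect, 0 of the 20 runs called a short RNA class, a gene list or a 6-mer. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.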

Results

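The data list regions of the genome of the nematode Caenorhabditis elegans recovered by precipitating the tagged Y53F4B.3 protein. Peaks are such regions, and whether the protein itself is bound at them was not tested separately. The worms, of strain RW12270, carried TY1, EGFP and 3xFLAG tags at the gene's own locus, placed there by CRISPR editing, and the tagged protein was precipitated with an antibody against GFP. In the annotation the gene is pole-4 (WBGene00013150), named after the small histone-fold subunit of DNA polymerase epsilon. Whole young adults, aged 64 h, were used after synchronisation as starved larvae, and the single group held 2 biological replicates. The comparisons therefore set peaks that passed the authors' reproducibility threshold against candidate regions that did not, and set the replicates against each other; worms without the tag were not analysed here. Replicate 1 had 287 listed peaks out of 18181 ranked candidates and replicate 2 had 248 out of 27101. For the series as a whole, a larger set of 465 peaks was drawn from 9477 candidates and a conservative set of 437 peaks from 12529. Listed peaks of the larger set had a median width of 260 bp. The read depth of the libraries is unknown here, since peak lists carry no counts. Positions are on assembly ce11, counted from 1.

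The strongest peaks lay mostly in intergenic sequence that occurs many times in the genome. Of the 20 listed peaks with the highest signal, 17 were intergenic, 15 had no protein-coding transcription start site (TSS) within 2000 bp, and 18 had a repeat share above 50%, the repeat share being the percentage of 24-mers within 130 bp of the summit that occur 5 or more times in the genome. The highest signal, 682, belonged to the peak at III:3770480-3770659, listed in replicate 2 but not in replicate 1. Next came III:2497906-2498086 with a signal of 662, I:13273637-13273840 with 655 and III:2499385-2499572 with 647, all listed in both replicates. The remaining intergenic peaks without a nearby TSS were III:3335049-3335223, III:1252520-1252698, V:14756648-14756835, I:6773016-6773184, X:1375139-1375398, X:2057930-2058082, IV:16458520-16458624, I:6773725-6773984, I:14686629-14686749 and I:6772553-6772812, with signals from 577 down to 291. The peak at V:10450526-10450606, with a signal of 316, lay in an intron.

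Of the top 20 peaks, 5 were assigned to a protein-coding gene. The ribosomal protein gene rpl-3 (WBGene00004414, III:3867854-3869587, plus strand) had a peak at III:3867506-3867648, in its promoter 268 bp upstream of the TSS, with a signal of 341 and a repeat share of 0. The chemoreceptor genes srh-246 and srv-14 had intergenic peaks 549 and 1831 bp upstream of their TSS, with signals of 529 and 486 and repeat shares of 71.0% and 88.2%. An intergenic peak 556 bp downstream of the TSS of sdz-19, past the 3' end of that gene, had a signal of 322, and a peak in a 5' UTR of the detoxification gene ugt-24, 557 bp downstream of its TSS, had a signal of 291. Both of these, like the srh-246 peak, were listed in replicate 2 and not in replicate 1.

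The tagged gene itself carried no listed peak. In the larger set, the candidate nearest to pole-4 (II:14968633-14969354, minus strand) was II:14966433-14966692, 1941 bp from the gene, with a signal of 34.2 and an irreproducible discovery rate (IDR) of 0.833. The nearest listed peak of that set, II:15165879-15166138, was 196525 bp away. Replicate 2 had 2 candidates inside pole-4, II:14968674-14968909 and II:14969113-14969348, with signals of 15.5 and 13.8 and IDRs of 0.638 and 0.972. Neither passed, and replicate 1 had no candidate closer than 899 bp.

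The promoters of rpl-3, rpl-35 and rps-24 were among the loci found in both replicates, which shared 127 peaks. This was 44.3% of the peaks of replicate 1 (95% interval 38.4 to 50.2%) and 51.2% of those of replicate 2 (44.8 to 57.6%), by exact binomial intervals that cover counting error only. A permutation of which ranked candidates counted as listed, done 1000 times in each replicate, gave a median of 1 shared peak and at most 5 (p = 0.001, the smallest that these draws can give). Of the 287 peaks of replicate 1, 94.4% overlapped a ranked candidate of replicate 2, and 79.8% of the 248 peaks of replicate 2 overlapped one of replicate 1. The strongest peaks of replicate 1 with no listed partner were M:13082-13308 in the mitochondrial gene WBGene00010967, with a signal of 951, M:13566-13794 in non-genic mitochondrial DNA, with 129, and X:1503865-1504124, assigned to F09E10.1, with 106. In replicate 2 they were III:3770468-3770663, with 623, III:3335040-3335231, with 519, and V:658201-658424, upstream of srh-246, with 488.

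In the larger set, 128 of 465 peaks (27.5%) were listed in both replicates, 130 only in replicate 1, 76 only in replicate 2 and 131 (28.2%) in neither list. Peaks at rpl-3, rpl-35, rps-24, rpa-2, hcp-3 and mcm-4 belonged to the first class, and those at rps-7, efl-1, hcp-1 and cye-1 to the last. Promoter summits made up 35.2% of the peaks listed in both replicates, 42.3% of those only in replicate 1 and 14.5% of those only in replicate 2, where 59.2% were intergenic. The mean repeat share was 24.2% for peaks in both, 15% for replicate 1 only, 52.5% for replicate 2 only and 11.4% for neither. The conservative set contained 356 of the 465 peaks (76.6%, 72.4 to 80.3%).

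Peaks listed in both replicates had the higher signal, with a median of 141 (quartiles 124 and 191, 128 peaks) against 93.1 (84.4 and 109.6, 337 peaks) for the others, a ratio of 1.52. The signal of the larger set comes from the same 2 replicates whose strength decides whether a peak is listed in each, so being listed in both selects for high signal, and the permutation test planned for this difference would only restate that selection, so its result is not given. Among the 206 peaks with a repeat share of 0 the ratio was 1.58. Peaks are not independent replicates of the animals, so every test over peaks describes these lists.

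Promoters, non-coding RNA genes and intergenic sequence held more of the listed summits than of the candidates that did not pass, and coding exons held far fewer. Promoters took 157 of 465 listed summits (33.8%, 29.5 to 38.3%) and 1873 of 8863 candidates (21.1%), an odds ratio of 1.90 (95% limits 1.55 to 2.33, adjusted exact p = 2.4e-09). Coding exons took 7 listed summits (1.51%) against 2028 candidates (22.9%), an odds ratio of 0.0515 (0.0206 to 0.107, adjusted exact p = 2.1e-39). Non-coding RNA genes took 45 listed summits (9.68%) against 196 (2.21%), an odds ratio of 4.74 (3.30 to 6.69, adjusted exact p = 2.3e-14). Intergenic summits numbered 139 (29.9% against 22.7%, odds ratio 1.45, adjusted exact p = 0.00079) and intron summits 98 (21.1% against 25.5%, odds ratio 0.779, adjusted exact p = 0.046), while 5' UTRs, with 4, and 3' UTRs, with 15, did not differ past the threshold (odds ratios 0.990 and 0.677). These are two-sided Fisher's exact tests, adjusted over 7 classes by the Benjamini-Hochberg method.

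**Figure D1:**
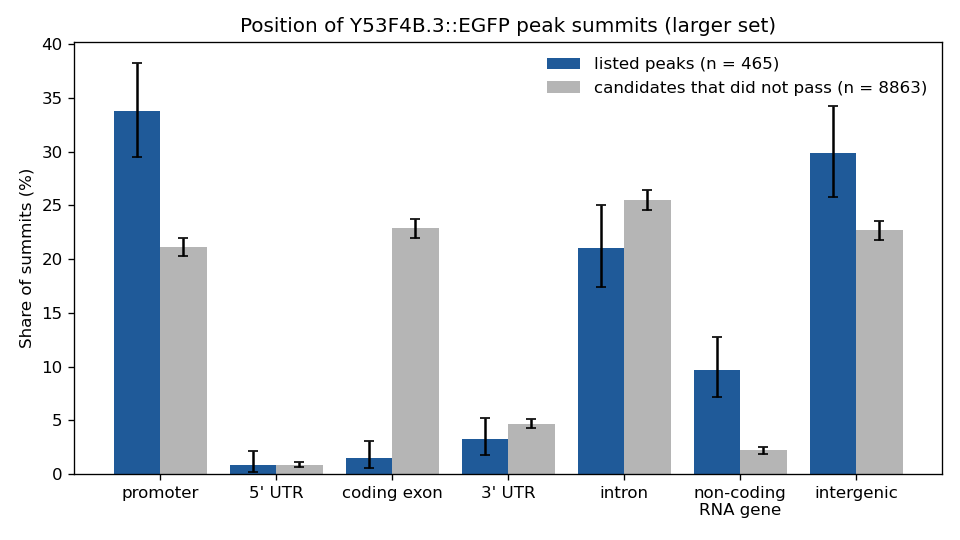
Share of peak summits (%) in each of 7 position classes, for the 465 listed peaks of the larger set and the 8863 candidates of the same ranked list that did not pass; error bars are exact binomial 95% intervals. Coding exons hold 1.51% of listed summits and 22.9% of the candidates, and promoters 33.8% and 21.1%.

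The promoter and coding exon differences were also past the threshold in each replicate's own lists, with promoter odds ratios of 2.57 in replicate 1 and 1.76 in replicate 2 and coding exon odds ratios of 0.0440 and 0.0759. Among summits with a repeat share of 0, the promoter odds ratio rose to 4.08, while that of non-coding RNA genes was 1.87 (adjusted exact p = 0.30) and that of intergenic sequence 0.782 (adjusted exact p = 0.30). The intergenic difference missed the threshold in replicate 1's own lists (1.24, adjusted exact p = 0.17) and the conservative set (1.13, adjusted exact p = 0.34) and was larger in replicate 2's (2.35) and with the left-out peaks added (2.95), while 3' UTRs passed it at an IDR of 0.001 (0.166, adjusted exact p = 0.0023) and with those peaks added (0.509, adjusted exact p = 0.0081). Over all summits the odds ratio of non-coding RNA genes was 2.81 (1.89 to 4.15) against candidates matched on chromosome and GC content. The intron difference was lost in the conservative set (0.835), with promoters of 1000 bp (0.806), with matched candidates (0.796), at a repeat share of 0 (0.676) and for peaks listed in both replicates (0.708). It was larger in replicate 2's lists (0.477) and without summits near short RNA genes (0.333, with 29 of 292 listed summits in introns). By the order of classes, a summit in a short RNA gene within an intron or promoter of a protein-coding gene counts there. The class of non-coding RNA genes therefore holds only part of such summits.

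Genes of tRNAs and of 3 other kinds of short RNA were over-represented near listed peaks. A tRNA gene lay within 500 bp of 24.1% of the 465 listed summits (20.3 to 28.2%) and of 316 of 8863 candidates (3.57%), an odds ratio of 8.58 (6.68 to 11.0, adjusted exact p = 1.1e-51). Genes of small nucleolar RNAs (snoRNAs), which guide the modification of ribosomal RNA, lay near 47 listed summits (10.1%) and 1.17% of candidates, an odds ratio of 9.46 (6.47 to 13.7, adjusted exact p = 6.4e-25). Small nuclear RNA (snRNA) genes lay near 10 listed summits (odds ratio 5.88, 2.57 to 12.3, adjusted exact p = 8.7e-05). Genes of the spliced leader (SL) RNA, which is trans-spliced onto worm messenger RNAs, lay near 5 (odds ratio 10.7, 2.80 to 35.7, adjusted exact p = 0.00073). MicroRNA genes, near 2 listed summits, and piRNA genes, near 17, did not differ past the threshold, with odds ratios of 1.00 and 1.25. Ribosomal RNA genes lay near none of the 465 summits, which allows a share of up to 0.790% by the exact interval, against 5 candidates. Of the 149 passing peaks left out of the thresholded list, 1 lay near a ribosomal RNA gene.

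In total 133 of the 634 annotated tRNA genes, 47 of 346 snoRNA genes, 11 of 99 snRNA genes and 5 of 30 SL RNA genes lay within 500 bp of a listed summit. Of the listed summits near tRNA genes, 81 fell inside the gene (72.3%, 63.1 to 80.4%), 25 upstream and 6 downstream, at a median of 24.5 bp from the 5' end. At snoRNA genes 37 of 47 summits lay upstream of the 5' end, at a median of -40 bp. The same medians were 24 bp for tRNA and -41.5 bp for snoRNA candidates that did not pass. Genes outside the naming rule, chosen after their values were seen, were the tRNA gene WBGene00014333 (X:9743589-9743660, summit inside it, signal 187), the snoRNA gene ZK994.7 (V:8500579-8500645, summit 13 bp upstream) and the SL RNA gene sls-2.8 (III:12250465-12250575, summit 54 bp upstream, signal 165).

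**Figure D2:**
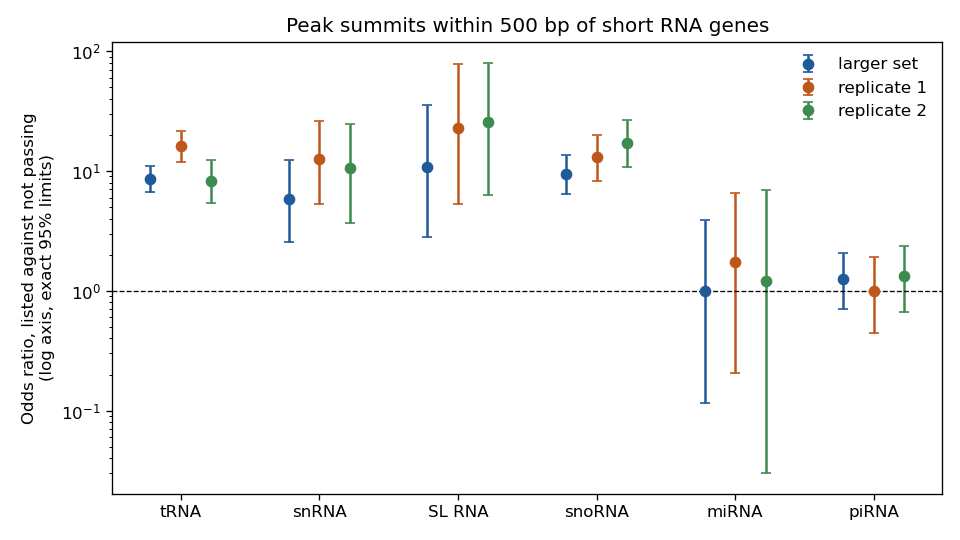
Odds ratio (log axis) of a peak summit lying within 500 bp of each class of short RNA gene, listed peaks against candidates that did not pass, in the larger set and in each replicate's own lists; bars are exact 95% limits, the dashed line marks 1, and rRNA genes, near none of the listed summits, are left out. The tRNA odds ratios are 8.58, 16.1 and 8.26 in the 3 lists, and those of microRNA and piRNA genes have limits on both sides of 1.

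All 4 of these classes were past the threshold in both replicates' own lists, where the odds ratios were 16.1 and 8.26 for tRNA, 13.1 and 17.2 for snoRNA, 12.5 and 10.5 for snRNA and 22.9 and 25.7 for SL RNA genes in replicates 1 and 2. For peaks listed in both replicates the tRNA odds ratio was 4.42, with 18 of 128 summits near a tRNA gene. Among summits with a repeat share of 0, the snoRNA odds ratio was 19.2 with 42 of 206 listed summits, and the tRNA odds ratio was 4.63 (1.60 to 11.1) with 6. That of SL RNA genes was 27.6 (5.44 to 129) with 4, while snRNA genes, near 1, missed the threshold (adjusted exact p = 0.36).

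Genes for ribosomal proteins and for the cell cycle and DNA replication had listed peaks more often than other genes. Of 318 genes assigned a listed peak, 9 were ribosomal protein genes, against 37 of 4497 genes with only non-passing candidates, an odds ratio of 3.51 (1.48 to 7.49, adjusted exact p = 0.039). These were rpl-3, rpl-35, rps-24, rpl-15, rps-28, rps-1, rpl-7A, rpl-12 and rps-7, and each summit lay in the promoter. The peak of rpl-35 (WBGene00004449, III:7855134-7855646) at III:7854634-7854744 had a signal of 248 and that of rps-24 (WBGene00004493, IV:385887-386606) at IV:385424-385683 a signal of 215, with summits 440 and 333 bp upstream of the TSS.

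Cell cycle and replication genes numbered 9 of the 318 against 15 of the 4497, an odds ratio of 8.69 (3.33 to 21.4, adjusted exact p = 0.00033). The strongest was at rpa-2 (WBGene00019767, I:4770292-4771358), a subunit of the single-stranded DNA binding replication protein A, at I:4769552-4769811 with a signal of 179.7, intergenic and 610 bp upstream of the TSS. The centromeric histone gene hcp-3 (WBGene00001831, III:9615306-9616470) had a peak at III:9616950-9617209 with a signal of 129, also 610 bp upstream. The peak assigned to the replicative helicase subunit gene mcm-4 (WBGene00003156, I:2318291-2321817), at I:2318113-2318372 with a signal of 128, lay in a 3' UTR of the neighbouring gene ekl-7, and its nearest TSS was that of a short transcript at the 3' end of mcm-4. The other members were zen-4, cya-1, efl-1, hcp-1, cye-1 and rnr-1. The cye-1 summit, in an intron, was next to the tRNA gene WBGene00022955, and the zen-4 summit lay near a snoRNA gene.

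Both lists were past the threshold in each replicate alone, with odds ratios of 4.82 and 9.58 for ribosomal proteins and 10.9 and 13.3 for cell cycle and replication in replicates 1 and 2. The second list missed it when only a TSS within 500 bp counted (6.26, adjusted exact p = 0.050) or an IDR of 0.001 was required (6.59, adjusted exact p = 0.080), and the first when passing peaks left out by the authors were added (3.30, adjusted exact p = 0.056).

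None of the other 27 lists passed. Germline and oocyte genes had 5 members with a listed peak, cpg-1, pos-1, mex-1, cbd-1 and egg-1, an odds ratio of 3.11 (0.916 to 8.43, p = 0.034, adjusted exact p = 0.33). Against all protein-coding genes in place of genes with a candidate, this list passed, with an odds ratio of 7.64 (adjusted exact p = 0.0077), and those of ribosomal proteins and of cell cycle and replication rose to 7.71 and 19.1. Detoxification enzymes also had 5 (2.55, adjusted exact p = 0.46), cuticle collagens 4 (1.96), chromatin regulators 3 (2.03), histones 3 (2.67), F-box proteins 3 (1.06) and chemoreceptors 10 (0.968). Translation factors, spliceosome, chaperone, nuclear hormone receptor, meiosis and sperm genes had 2 each. Respiratory chain, homeobox, C-type lectin, intestine, neuropeptide and insulin, TGF-beta and dauer pathway genes had 1 each. No listed peak was assigned to the body wall muscle, neuron, pharynx, hypodermis regulator, proteasome, aminoacyl-tRNA synthetase, innate immunity or lysosome and autophagy lists, which had between 3 and 22 genes with non-passing candidates only, so that a share of up to 1.15% of the 318 genes is allowed for each by the exact interval. Whole worms were used, so a list of tissue genes assigns no peak to a tissue.

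Chromosome IV held 100 of the 465 listed peaks (21.5%) against 16.8% of the candidates, an odds ratio of 1.36 (1.07 to 1.71, p = 0.011, adjusted exact p = 0.067). None of the 6 chromosomes passed the threshold by Fisher's exact test, and 1 had an unadjusted p under 0.05. Chromosome X held 69 listed peaks (14.8% against 12.4%, odds ratio 1.24, 0.936 to 1.61), and with the left-out peaks added it was over-represented (1.57, adjusted exact p = 0.00058). Among summits with a repeat share of 0, X held 5 of 206 listed peaks (2.43%) against 847 of 6994 candidates (12.1%), an odds ratio of 0.181 (0.0578 to 0.430, adjusted exact p = 9.2e-06). In replicate 1's own lists chromosome V was under-represented (odds ratio 0.629, adjusted exact p = 0.040).

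Sequence words of tRNA genes had the smallest p-values among the 6-mers over-represented at listed summits of the larger set. CGAACC, on either strand within 50 bp of the summit, was present at 77 of 465 listed peaks (16.6%) and at 143 of 2325 candidates matched for GC content (6.15%), an odds ratio of 3.03 (2.22 to 4.11, adjusted exact p = 1.0e-08). GTTCGA, a word of the internal promoter box B of tRNA genes, followed with 86 peaks (18.5% against 8.47%, odds ratio 2.45, adjusted exact p = 1.3e-06). CGAACC was present at 62 of the summits near a tRNA gene (55.4% of them) and at 1 of 127 promoter summits with no short RNA gene nearby. At those promoters CGAAAA was present at 41 (32.3%), CGCGCC at 33 (26%), ACGAAA at 32 (25.2%) and ACCGTA at 31 (24.4%). At the 165 listed summits outside promoters with no short RNA gene of these 4 kinds nearby, CGAAAA was present at 43 (26.1%), ACGAAA at 30 (18.2%), ACCGTA at 15 (9.09%) and CGCGCC at 10 (6.06%). GAGTAA was present at 27 of these 165 (16.4%) and TCTAGA at 22 (13.3%), against 2 and 5 of the 127 promoter summits. All these words were picked from the same peaks, and their shares at candidates by position were not computed, so the shares by position show no enrichment.

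Of 2080 6-mers, 239 differed past an adjusted p of 0.05 by two-sided Fisher's exact tests, of which 120 were under-represented. The candidates were matched on GC content but not on position, and listed summits held more promoters and fewer coding exons. The odds ratios of words therefore do not separate a word from the position of its summits. Without the summits near tRNA, snRNA, SL RNA or snoRNA genes, ACGAAA had the smallest p, with 62 of 292 peaks (21.2% against 7.26%, odds ratio 3.44, 2.40 to 4.91, adjusted exact p = 4.8e-08), followed by ACCGTA (odds ratio 4.14) and CGCGCC (3.83), while CGAACC (1.05) and GTTCGA (0.873) were no longer past the threshold. The word with the smallest p was GAGTAA in replicate 2's own lists (odds ratio 6.62, against 3.34 in the larger set). It was ACGAAA at an IDR of 0.001 (3.23), CAGAAC for peaks listed in both replicates (4.71) and GCCAGAGA among 8-mers (25.3). GAGTAA was also first with the left-out peaks added (8.43), whose median repeat share was 88.2%. At a repeat share of 0 the first word was CTGGAA, which was under-represented (0.0387). Whether copies of a repeat carry these words was not tested. GTTCGA missed the threshold in replicate 2's own lists (1.63, adjusted exact p = 0.23), and with a repeat share of 0 so did CGAACC (1.49, adjusted exact p = 0.69).

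Passing peaks that the authors' thresholded list leaves out lay mostly in repeated sequence. Besides the 465 listed peaks, 149 candidates of the larger set had an IDR of 0.01 or less and were not listed. Of these, 146 were intergenic, and the strongest, X:110357-110623, 1475 bp upstream of elk-2, had a signal of 5424. Their median signal was 275 against 103.2 for listed peaks, and their median repeat share 88.2% against 9.66%.

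**Figure D3:**
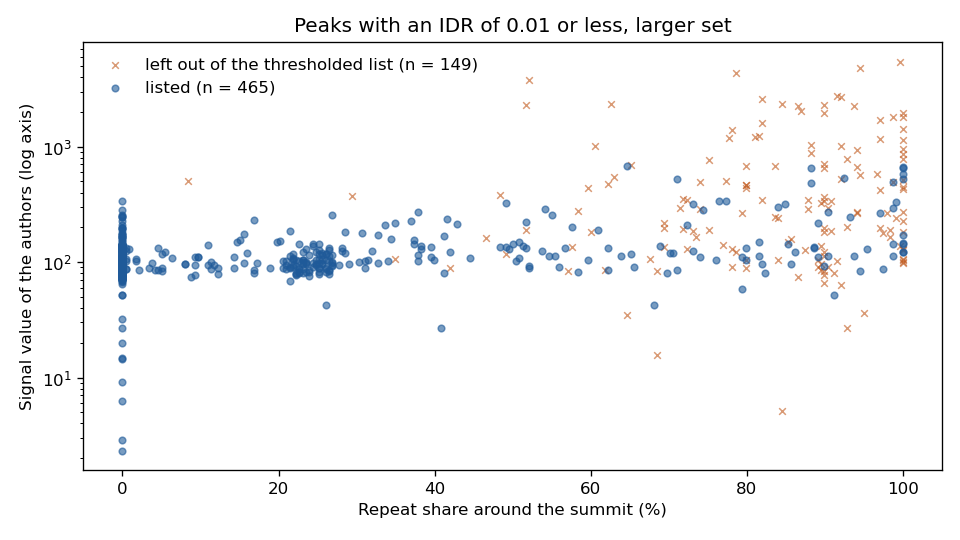
The authors' signal value (log axis) against the repeat share around the summit (%) for each peak of the larger ranked list with an IDR of 0.01 or less; circles are the 465 listed peaks and crosses the 149 peaks left out of the thresholded list. The crosses have a median repeat share of 88.2% and reach a signal of 5424, and the circles a median of 9.66% and at most 682.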

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

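Both tests below were chosen before the repeat shares and overlaps they measure were computed, but after the left-out peaks had been noticed. In the larger set, 149 peaks with an IDR of 0.01 or less are missing from the thresholded list. Their median repeat share was 88.2%, against 9.66% for listed peaks, so repeated sequence is a candidate explanation for their high signal, and reads that map to many copies could add to it. None of the 149 overlapped a listed peak of any of the 4 lists (0%, where 3 counts of the total, or 2.01%, is taken as the limit for a count of 0), which fits fixed regions being left out of every list. By definition the 149 are not listed in the larger set, so mainly the other lists bear on this. Of the 149, 136 also met a left-out peak of replicate 2 and 74 one of replicate 1. What stays open is whether the tagged protein is also bound there, since worms without the tag were not analysed here and no biological explanation was tested.

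Replicate 1 listed 2 mitochondrial peaks, M:13082-13308 with a signal of 951 and M:13566-13794 with 129, while the larger set, the conservative set and replicate 2 ranked none there. The first was the strongest peak of replicate 1 without a partner in replicate 2.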

How the results depend on the processing

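Settings not among those fixed in advance, chosen after seeing the data, are the IDR of 0.001, the added left-out peaks, peaks listed in both replicates, the repeat share of 0 and the removal of summits near short RNA genes. Of 132 alternative values of the leading results, 108 kept their direction and side of the threshold or stayed within their interval or 1.5 times, and of 442 for single classes, lists and words, 408 did; the planned IDR of 0.01 removes no peak and is not counted. The cause of the changes below was not tested unless stated. At an IDR of 0.001, the share of replicate 2's peaks found in replicate 1 was 44.4%, the share of the larger set in the conservative set 65.2%, the cell cycle and replication odds ratio 6.59, the number of gene lists past the threshold 1 and of 6-mers 114. With a repeat share of 0, replicate 2's shared peaks were 63.9%, position classes past the threshold 2, chromosomes 1, 6-mers 57, and odds ratios 1.87 for non-coding RNA genes, 0.782 for intergenic summits and 0.181 for X. With the left-out peaks added, 3 chromosomes, 1 gene list and 570 6-mers passed, and the ribosomal protein odds ratio was 3.30. Without summits near short RNA genes the non-coding RNA gene odds ratio was 0.853, by construction, GTTCGA stood at 0.873 and ACCACT at 0.985, and 132 6-mers passed. Peaks listed in both replicates gave 5 6-mers, with fewer peaks tested. The conservative set gave 3 position classes. All protein-coding genes as background brought in the germline and oocyte list, at 7.64. A start site within 500 bp gave a cell cycle and replication odds ratio of 6.26 and 1 list. Flanks of 100 bp gave 400 6-mers and unmatched candidates 498. Across the lists without replicate 1 and without replicate 2, 0 to 1 chromosomes and 153 to 178 6-mers passed. The lists carry no read counts, so what depth limits could not be measured.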

Other observations

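The comparisons of chromosome X by kind of summit, of divergent promoters and of the replicates' make-up, and the TTTSSCGC test, were chosen only after the result was seen, and for 2 tests the bound that decides was also changed then, as stated with each. Listed peaks outside repeated sequence were rare on chromosome X. With a repeat share of 0, X held 2 of 127 listed peaks of replicate 1 (1.57%, against 14.2% of its candidates, odds ratio 0.0967, adjusted exact p = 6.9e-06) and 2 of 83 of replicate 2 (2.41% against 15.7%, odds ratio 0.132, adjusted exact p = 0.00047), by Fisher's exact tests adjusted over 24 comparisons. Promoter summits gave the same direction, with 5 of 157 listed promoter peaks of the larger set on X (3.18% against 8.22%, odds ratio 0.367, adjusted exact p = 0.034). Summits with a repeat share above 0 went the other way in the larger set, with 64 of 259 on X (24.7% against 13.3%, odds ratio 2.14, 1.54 to 2.95) and in replicate 1 (2.39), but not past the threshold in replicate 2 (15.8% against 12.7%, odds ratio 1.29, adjusted exact p = 0.28). Of the listed summits near a tRNA gene 56 (50%) were on X, against 44.6% of the candidates near one (adjusted exact p = 0.40). These 56 were most of the 69 listed peaks on X in the larger set. Only 5 of the 69 had a repeat share of 0, so most of the 64 on X above it lay near a tRNA gene. The excess on X above a repeat share of 0 therefore cannot be separated from the peaks near tRNA genes. It was not tested without them.

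Listed promoter peaks lay more often between divergent genes. A start site on each strand was in promoter range of 40 of 157 listed promoter summits (25.5%) and of 231 of 1873 promoter candidates (12.3%), an odds ratio of 2.43 (1.61 to 3.61, Fisher's exact p = 2.3e-05). The median listed promoter summit lay at -201 bp from its start site, against -150 bp for the candidates. The make-up of the replicates' lists is given as shares only, since each is 1 library and the 127 shared peaks are in both. A tRNA gene was near 74 of 287 peaks of replicate 1 (25.8%) and 31 of 248 of replicate 2 (12.5%), promoters held 37.3% and 26.6% and intergenic sequence 27.2% and 44%, while snoRNA genes were near 10.1% and 10.9%.

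Replicate 2 listed 121 peaks that replicate 1 did not, such as the one upstream of srh-246. Their mean repeat share was 45.9%, against 24.5% for the 127 shared peaks, a difference of 21.3 percentage points (95% bootstrap interval 12.9 to 29.8, permutation p = 2.0e-05), so repeated sequence may account for part of this set. Loss just under the threshold in replicate 1 is unlikely to be the whole cause, since 50 met no candidate of replicate 1. A non-passing candidate was met by 58.7% (49.4 to 67.6%), below the 80% set in advance for this cause. A candidate at any IDR counted, so these need not lie near the threshold. In the other direction, 144 of replicate 1's 160 own peaks (90%) met a non-passing candidate of replicate 2, whose ranked list is longer. The bound written against near-threshold loss in replicate 1, under 50%, was not met. Excluding the 80% was made the deciding rule after the value was seen. A difference between the worm cultures or libraries stays open and was not tested.

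The peaks near tRNA genes could come in part from reads shared between gene copies. Among summits with a repeat share of 0 the odds ratio was 4.63, with limits of 1.60 to 11.1 that span the bound of 2 set for this cause, so 6 listed summits are too few to decide. A general avoidance of gene bodies is unlikely to be the whole cause: with promoter, non-coding RNA gene and intergenic summits kept in both sets, the odds ratio was 5.52 (3.99 to 7.57, 67 of 341 against 173 of 4080), above the bound of 2. The bound written against it, a lower limit above 4, was narrowly missed, and excluding 2 was made the deciding rule after the value was seen. Whether the tagged protein binds tRNA, snoRNA, snRNA and SL RNA genes or whether any GFP precipitate recovers such highly transcribed loci stays open, since worms without the tag were not analysed here.

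Histone-fold proteins related to the tagged one bind the CCAAT box as part of the NF-Y complex, so it was a candidate source of the listed peaks. CCAAT was present within 50 bp of 75 of 465 listed summits (16.1%) and 451 of 2325 GC-matched candidates (19.4%). The odds ratio was 0.799 (0.603 to 1.05, Fisher's exact p = 0.10), which argues against the CCAAT box for the listed peaks as a whole. Promoter peaks were not tested alone for this word. A second hypothesis was that sites like those of the cell cycle regulator E2F, TTTSSCGC with S for C or G, might mark the cell cycle and replication genes. The word stood at 3 of their 9 peaks, of which only 4 lie in promoters, and at 20 of the 153 listed promoter peaks of other genes, an odds ratio of 3.29 (0.494 to 17, Fisher's exact p = 0.12). The sets differ in position and the peaks are few, so this decides nothing. Over all listed peaks it was present at 31 of 465 (6.67%) against 63 of 2325 matched candidates (2.71%). The odds ratio was 2.56 (1.59 to 4.06, Fisher's exact p = 9.8e-05). These candidates were matched on GC content and not on position. Promoters held 33.8% of listed summits and 21.1% of all non-passing candidates, so this odds ratio does not separate the word from position.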
